A study of Mus musculus with 9 samples.

How the data were processed

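RNA from 3 populations of myeloid cells of normal mouse bone marrow was measured on 9 Affymetrix mouse expression arrays, 3 per population. Per the labels' protocols, marrow of C57BL/6 mice aged 4 to 10 weeks, of either sex, was first parted with magnetic beads into cells with and without c-kit. Cells with c-kit and Gr1 that lacked a set of antigens of the lymphoid and erythroid lineages (B220, CD3, CD4, CD8, TER119, IL7Rα) were then sorted by flow cytometry according to Mac1. By their cytology, the labels call both of these populations undifferentiated cells or myeloblasts. Mature neutrophils carried Gr1 and Mac1 and lacked c-kit. RNA was purified on columns, checked on a bioanalyzer, amplified in a two-cycle protocol and labelled with biotin, per the labels' protocols. Repeated amplification favours the 3′ ends of transcripts and can add spread between arrays. The labels do not say that replicates came from separate animals, nor give the age or sex behind an array. The p-values therefore measure only the spread between these samples, which may be technical.

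The authors deposited one table of intensity values on a linear scale, with 45101 probe sets and 9 columns. Each column is named for its sample, whose title gives the population and a replicate number from 1 to 3. How the intensities were summarised, corrected for background and scaled, and with what software, is not given in the sources used here. No array's values were forced to the distribution of another: the mean intensity per array lies between 549.4 and 727.4 and the median between 39.1 and 61.8. Between 544 and 793 probe sets per array hold exactly 1, and between 2 and 9 lie below it. The number of arrays limits the precision. Between 36.3% and 41.1% of probe sets per array exceeded an intensity of 100.

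Values were used as deposited, and log2(intensity + 16) was taken. Differences of dim genes are therefore understated. Probe sets were named through the platform annotation. Of all probe sets 34945 name 1 gene, 932 name several and 9160 name none, and 64 are controls. Only those with 1 gene were named. By gene ID, 99.4% of them were matched to a gene table of the assembly GRCm38.p6, used for names only, and 0 symbols changed. For the 9009 genes with several probe sets the one with the highest mean over all 9 arrays was kept, which gave 18194 genes. Control probe sets stayed out of the tests and served as checks of the arrays. Probe sets without a gene were tested in a fit of every probe set, where 223 of 9160 were called for Mac1+ against Mac1lo, 2969 for neutrophil against Mac1+ and 3304 for neutrophil against Mac1lo.

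Differences were tested with limma 3.58.1 in R 4.3.3, in a single linear model of the 3 populations with moderated variances, so that all 9 arrays share 1 estimate of the spread. Genes with an adjusted p under 0.05 (Benjamini-Hochberg over the 18194 genes of a comparison) were called. At an unadjusted p under 0.05 the comparisons gave 3960, 9829 and 10452 genes. Gene lists were tested with camera, a limma function that compares a list's genes with all others. It used a preset correlation of 0.01 between genes and adjustment over 99 tests (33 lists in 3 comparisons), and was repeated with the correlation estimated from the data. Of 669 list members 596 were measured. Each list's genes were also adjusted over the list alone. The lists covered granule classes, chemotaxis receptors, the NADPH oxidase, stem and progenitor genes, myeloid transcription factors, DNA replication, mitosis, ribosomes, energy metabolism, cholesterol and nucleotide synthesis, the interferon response, chromatin, MLL leukaemia regulators, the Bcl2 family, inflammation, stress, the nuclear lamina, autophagy and markers of other marrow cells. Sex genes were counted without a camera test. Ly6g, which encodes a Gr1 antigen, was not analysed here.

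Named genes follow a rule. In each comparison they are the sort markers, and the 10 genes with the largest positive and the 10 with the largest negative difference among called genes whose groups did not overlap and whose mean in the higher group was above the median gene. For each list they are up to 4 called members with the largest differences, or the 2 with the smallest p where none was called, and the text gives some of these. Lists, tests, this rule and the alternatives were chosen before the data were examined. The alternatives were a replicate block, quantile normalization, centring of each array on its median, offsets of 1 and 64, leaving out genes under the 40th percentile of mean level (called dim genes), the mean of a gene's probe sets, every probe set on its own, and leaving out probe sets marked as able to bind several transcripts (suffix x or s). Others were a trended and robust variance prior, a fit of only the 2 populations compared, array weights, an estimated correlation, a change of at least 2-fold, and leaving out each array in turn.

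The procedure was tested on simulated data of 18194 genes, in 10 draws per comparison with 100 genes changed by a log2 of 1 and 100 by a log2 of 2. With the spread each array has, 41.9% of the smaller and 90.8% of the larger changes were recovered for Mac1+ against Mac1lo, and 0.15% of calls were false. For neutrophil against Mac1+ these were 42.2%, 89.1% and 15.6%, and for neutrophil against Mac1lo 39.0%, 89.4% and 11.4%. With equal spread in all arrays the share of false calls was 5.45%, 4.95% and 5.22%. On average 0 lists were called per draw. The simulated genes varied independently of each other, so this does not test the list calls where genes are correlated. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.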

Results

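Transcript levels were measured in 3 myeloid cell populations sorted from the bone marrow of normal C57BL/6 mice, a standard inbred strain, with 3 microarrays for each population and 9 in all. The mice were of either sex and 4 to 10 weeks old. Both immature populations carried c-kit, the receptor for stem cell factor found on stem and progenitor cells, and Gr1, a surface antigen of the granulocyte lineage. They differed in Mac1, an adhesion receptor whose alpha chain is encoded by Itgam, and are called Mac1lo cells (Mac1 low or absent) and Mac1+ cells. The mature population, neutrophils, carried Gr1 and Mac1 without c-kit. Each array gave one intensity for each of 45101 probe sets, with a median between 39.1 and 61.8 and a maximum between 18326 and 22749. The number of arrays limits the precision of every value. Values are means ± SD of log2(intensity + 16) over 3 arrays, and differences are on the same log2 scale ± standard error, so they understate the change of dim genes. The first principal component of the 18194 genes held 78.4% of the variance and separated neutrophils from both c-kit+ populations. The next, which held 9.42%, separated Mac1lo cells (scores from -32.1 to -27.1) from Mac1+ cells (28.1 to 33.6). It also set neutrophil array 1 (-64.5) apart from neutrophil arrays 2 and 3 (23.1 and 37.3).

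**Figure D1:**
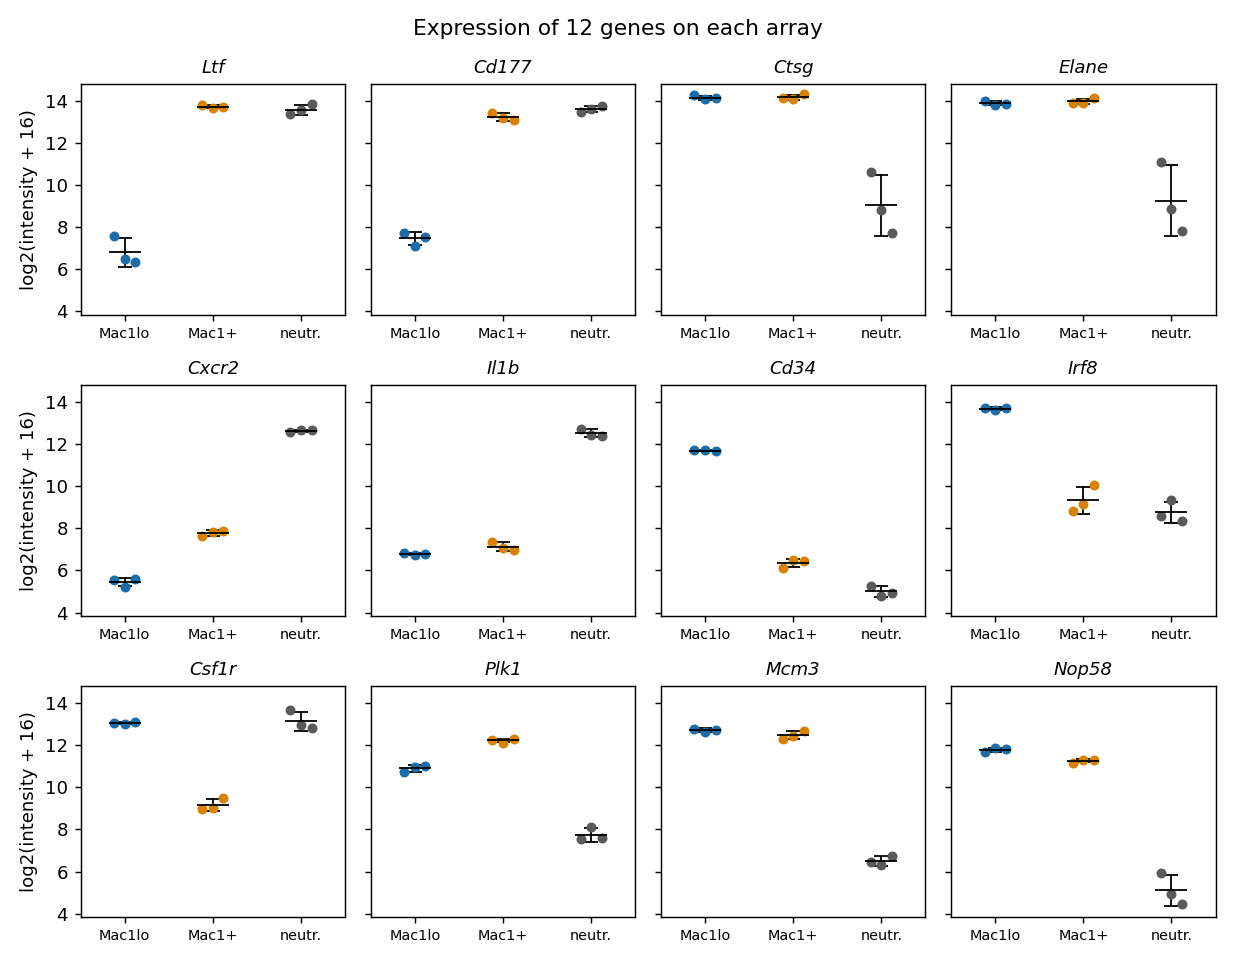
Log2(intensity + 16) of 12 genes in the 3 populations, where points are single arrays, dashes are means and bars are SDs (n = 3). Ltf and Cd177 stood near 13 in Mac1+ cells and near 7 in Mac1lo cells, while Ctsg and Elane were near 14 in both c-kit+ populations and near 9 in neutrophils.

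The first comparison set Mac1+ against Mac1lo cells, and so asked how c-kit+ Gr1+ cells differ once they carry Mac1. Transcripts of secondary granule proteins, the antimicrobial contents of a granule made at the intermediate stages of neutrophil development, were far higher in Mac1+ cells. Ltf, which encodes the iron-binding protein lactoferrin, was 119.5-fold higher (13.71 ± 0.07 against 6.81 ± 0.69, n = 3 each, difference 6.90 ± 0.31, adjusted p = 2.89e-06), and Cd177, a neutrophil surface glycoprotein, was 54.5-fold higher (difference 5.77 ± 0.19, adjusted p = 8.39e-07). The level of Ltf in Mac1+ cells is near the top of the scale, where differences may be compressed, so its fold may be understated. Compression was not tested. Cd34, a sialomucin of stem and progenitor cells, fell by 5.35 ± 0.17 (from 11.69 ± 0.03 to 6.35 ± 0.19, adjusted p = 8.39e-07). Irf8, a transcription factor required for monocyte and dendritic cell development, was 20.4-fold lower in Mac1+ cells (difference -4.35 ± 0.34, adjusted p = 5.27e-05). Kit itself stood at 11.71 ± 0.06 and 11.63 ± 0.06 (difference 0.08 ± 0.38, adjusted p = 0.969), and Itgam, which encodes the antigen used for the sort, was 3.23 ± 0.24 higher in Mac1+ cells.

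Of the 15 secondary granule genes, 13 rose and 2 did not pass (14 rose when adjusted over the list alone). The list rose against all other genes in the camera test (adjusted p = 1.65e-23, and 0.0136 with an estimated correlation). Chil1, a chitinase-like granule protein, rose 47.0-fold, Itgb2l, an integrin beta chain found in neutrophil precursors, rose 42.2-fold, and the cathelicidin-related gene Ngp rose 28.8-fold. Tertiary granule genes, which encode proteins of the gelatinase granule and of the later neutrophil stages, numbered 9, of which 4 rose, 1 fell and 4 did not pass (6 rose and 1 fell when adjusted over the list alone). Mmp9, gelatinase B, rose by 4.92 ± 0.49 and the formyl peptide receptor gene Fpr2 by 4.10 ± 0.30, whereas Hpse, which encodes heparanase, fell by 2.43 ± 0.35. Without Mac1lo array 1 the difference of Mmp9 was 5.56. As a list they rose (adjusted p = 0.00298), a call lost at adjusted p = 0.0924 with an estimated correlation. Itgam, whose antigen was used for the sort, is in this list and in that of the receptors, so its rise is not independent of the sort. Fpr2 is also in both, and Cybb is in the secondary granule and NADPH oxidase lists, so these lists are not separate evidence. Among 22 chemotaxis and surface receptor genes, 14 rose, 3 fell and 5 did not pass (15 rose and 3 fell when adjusted over the list alone). C5ar1, the receptor for complement fragment C5a, rose 24.3-fold and Il1r2, a decoy receptor for interleukin-1, rose 18.8-fold. Camera called the list higher (adjusted p = 6.45e-10), but not with an estimated correlation (adjusted p = 0.0698). Of 7 genes of the NADPH oxidase, the enzyme complex of the respiratory burst, 6 rose and 1 did not pass (6 when adjusted over the list alone), with Cybb up by 1.93 ± 0.16 and Ncf4 by 1.28 ± 0.17. That list rose at adjusted p = 3.54e-08, a call lost at adjusted p = 0.077 with an estimated correlation. Primary granule genes, made at the promyelocyte stage, were not called as a list (adjusted p = 0.856), with a median of 0.06, a mean of -0.11 and a downward test. Their median level, 13.64 to 14.03 on the 6 arrays, is near the top of the scale, where differences may be compressed, which was not tested. Of 8, only Ctsc, the protease that activates granule serine proteases, passed, with a difference of -1.85 ± 0.24 (1 gene also when adjusted over the list alone).

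Monocyte and macrophage marker genes fell from Mac1lo to Mac1+ cells. Of 20 measured, 13 fell, 1 rose and 6 did not pass (14 fell and 1 rose when adjusted over the list alone). The list fell at adjusted p = 1.04e-08, and just passed with an estimated correlation (adjusted p = 0.04998). The lysosomal protease gene Ctss fell by 4.76 ± 0.17, and Ly86, a partner of a Toll-like receptor homologue, by 4.48 ± 0.40. Csf1r, the receptor for macrophage colony-stimulating factor, fell by 3.88 ± 0.24. Dendritic cell markers fell as a list (adjusted p = 0.022, and adjusted p = 0.124 with an estimated correlation), but only 2 of 14 passed, Flt3 and Bst2 (3 when adjusted over the list alone). Bst2 did not pass when Mac1lo array 1, 2 or 3 or Mac1+ array 1 or 3 was left out (adjusted p = 0.0616 to 0.0887), nor with quantile normalization, centred arrays or an offset of 1 (0.0554 to 0.112). The call of the list ended with quantile normalization (adjusted p = 0.0747) and without dim genes (adjusted p = 0.155). Stem and progenitor genes counted 6 lower, 1 higher and 18 not passed of 25 (8 lower and 1 higher when adjusted over the list alone). Next to Cd34, the transcription factor gene Sox4 fell by 3.36 ± 0.63 and the cytokine receptor gene Flt3 by 2.18 ± 0.28. Their list fell (adjusted p = 0.000376, and adjusted p = 0.0698 with an estimated correlation). Of 21 myeloid transcription factor genes, 10 rose, 4 fell and 7 did not pass (11 and 4 when adjusted over the list alone). Id2, an inhibitor of basic helix-loop-helix factors, rose by 4.02 ± 0.17 and Mxd1, a Myc antagonist, by 2.71 ± 0.15. Together they rose at adjusted p = 0.00804. That call was lost at adjusted p = 0.209 with an estimated correlation, at 0.0875 with arrays centred on their medians and at 0.0502 without dim genes.

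Mitosis genes were higher in Mac1+ cells, with 12 of 32 up, 20 not passed and 24 up when adjusted over the list alone (adjusted p = 3.22e-12, and adjusted p = 0.232 with an estimated correlation). Ube2c, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, rose by 1.87 ± 0.35 and the mitotic kinase gene Plk1 by 1.32 ± 0.19. By contrast, 34 of 36 DNA replication genes did not pass and 2 fell (1 when adjusted over the list alone), and the list was not called (adjusted p = 0.216), though it passed with quantile normalization (adjusted p = 0.0208). Ribosome biogenesis genes were lower, with 7 of 29 down, 22 not passed and 16 down when adjusted over the list alone (adjusted p = 4.18e-09, and adjusted p = 0.102 with an estimated correlation). Gnl3, a nucleolar GTPase, fell by 1.01 ± 0.22, with adjusted p = 0.0161 and 0.0525 to 0.0686 when any 1 of the 6 c-kit+ arrays was left out. Of 19 nucleotide and one-carbon genes, 4 fell and 15 did not pass (7 fell when adjusted over the list alone). This list fell at adjusted p = 0.000113, and had adjusted p = 0.102 with an estimated correlation. Psat1, an enzyme of serine synthesis, fell by 0.86 ± 0.16 (adjusted p = 0.00854), and its call was lost when probe sets that can bind several transcripts were left out (adjusted p = 0.0676).

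The remaining functional lists were not called in this comparison. Interferon response genes went both ways, with 6 of 19 higher, 7 lower and 6 not passed (6 and 7 when adjusted over the list alone, adjusted p = 0.73). Their median was 0.06, their mean -0.22 and the test downward. They ranged from Ddx58, a sensor of viral RNA, at 2.07 ± 0.28 to Ifitm1, an interferon-induced membrane protein, at -3.33 ± 0.17. Inflammatory signal genes counted 4 higher and 5 lower of 20 (7 and 5 when adjusted over the list alone, adjusted p = 0.714). Il1rn, the interleukin-1 receptor antagonist, was up by 1.37 ± 0.20 and the inflammasome gene Nlrp3 down (difference -1.36 ± 0.18). Of 18 stress and immediate early genes, 2 rose and 2 fell (the same numbers when adjusted over the list alone, adjusted p = 0.925). Chromatin regulators had 4 of 25 lower (4 when adjusted over the list alone, adjusted p = 0.581), among them the DNA methyltransferase gene Dnmt3b at -1.16 ± 0.21. Of 6 regulators known from the stem cells of MLL leukaemia, 2 fell (2 when adjusted over the list alone, adjusted p = 0.281). Regulators in it were named in leukaemia work that used these populations, so its direction is not independent evidence. It passed with an offset of 64 (adjusted p = 0.0289) and with the mean of a gene's probe sets (0.0245). Those that fell were Mef2c, at -1.84 ± 0.36, and Hoxa9, at -2.19 ± 0.44, whose call was lost without Mac1lo array 2 or Mac1+ array 1 (adjusted p = 0.0509 and 0.0531) and with an offset of 1 (0.055). Ribosomal protein genes (2 of 31 lower), oxidative phosphorylation (1 of 34) and the tricarboxylic acid cycle (1 of 16) had adjusted p = 0.44, 0.102 and 0.129, with 1, 0 and 1 lower when adjusted over the list alone. With quantile normalization the latter pair passed (adjusted p = 0.000735 and 0.0107). Oxidative phosphorylation also passed without Mac1lo array 2 (0.0494) or neutrophil array 1 (0.0485), with a trended variance prior (0.0395) and in a fit of only these 2 populations (0.0387).

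Over all 18194 genes, limma called 1148 higher and 1003 lower in Mac1+ than in Mac1lo cells, 11.8% of the genes. Among genes with the largest differences outside these lists, Lrg1, a leucine-rich glycoprotein of granulocytes, was 4.82 ± 0.14 higher. Il6st, the signalling chain shared by receptors of the interleukin-6 family, fell by 5.45 ± 0.30. The annexin partner S100a10 had a difference of -4.96 ± 0.38 and the receptor tyrosine kinase gene Met one of -4.64 ± 0.45. Of the 33 lists tested, 11 were called, and 2 of them, secondary granule and monocyte genes, also with an estimated correlation. The share of calls that were higher was 53.4%, and 70.7% when each array was centred on its median, which moved the median of all genes from -0.01 to 0.17. The number higher was 719, 710, 747 and 752 without Mac1lo array 2, Mac1lo array 3, Mac1+ array 2 and Mac1+ array 3. The number lower was 658, 599, 607 and 658 without Mac1lo arrays 1, 2 and 3 and Mac1+ array 1. Both were larger, 2190 and 1986, without neutrophil array 1, whose spread enters the shared error estimate.

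The next comparison set mature neutrophils against Mac1+ cells, the c-kit+ population that shares both of their sort antigens. DNA replication genes were lower in neutrophils and interferon response genes higher. Mcm3, a subunit of the replicative helicase, was 63.3-fold lower (6.50 ± 0.23 against 12.49 ± 0.19, n = 3 each, difference -5.98 ± 0.17, adjusted p = 4.04e-08). Bst1, an ectoenzyme anchored to the surface of myeloid cells, was 204.7-fold higher (12.35 ± 0.12 against 4.68 ± 0.10, difference 7.68 ± 0.14, adjusted p = 2.33e-08), and Ifitm1 was 95.4-fold higher (difference 6.58 ± 0.17, adjusted p = 4.01e-08). Kit fell by 3.87 ± 0.38 (adjusted p = 2.47e-05) and Itgam rose by 1.86 ± 0.24 (adjusted p = 0.000142).

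Every one of the 36 measured DNA replication genes fell, as all 36 did when adjusted over the list alone (adjusted p = 9.81e-19, and 0.0397 with an estimated correlation). Cdc6, which loads the replicative helicase, fell by 5.41 ± 0.25, and Pola1, the catalytic subunit of DNA polymerase alpha, by 5.20 ± 0.15. All 32 mitosis genes fell too, with 32 when adjusted over the list alone, among them the checkpoint kinases Bub1, at -5.23 ± 0.33, and Ttk, at -4.68 ± 0.15 (adjusted p = 1.35e-15, and adjusted p = 0.197 with an estimated correlation). Of 29 ribosome biogenesis genes, 27 fell, 1 rose and 1 did not pass (27 and 1 when adjusted over the list alone). Nop58 and Gar1, proteins of the small nucleolar particles that modify ribosomal RNA, had differences of -6.17 ± 0.32 and -5.65 ± 0.16. Camera called the list lower (adjusted p = 8.71e-12, and adjusted p = 0.0698 with an estimated correlation). Among ribosomal protein genes 29 of 31 fell and 2 did not pass (29 when adjusted over the list alone), led by Rpl14 at -4.26 ± 0.13 (adjusted p = 1.17e-08, and adjusted p = 0.37 with an estimated correlation). The median of this list was 12.8 on neutrophil array 1 and 12.1 and 11.9 on the other two.

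Nucleotide and one-carbon genes fell in 18 of 19 cases, 18 also when adjusted over the list alone (adjusted p = 2.18e-08, and 0.04998 with an estimated correlation), with Ctps, which makes CTP, and the purine synthesis gene Paics each 43.8-fold lower. Genes of oxidative phosphorylation fell in 31 of 34 cases (32 when adjusted over the list alone, adjusted p = 1.1e-08, and adjusted p = 0.197 with an estimated correlation), among them the ATP synthase subunit gene Atp5g1, at -3.95 ± 0.25. In the tricarboxylic acid cycle 14 of 16 genes fell (14 when adjusted over the list alone, adjusted p = 8.32e-06, and adjusted p = 0.227 with an estimated correlation), with Idh3a, a subunit of isocitrate dehydrogenase, at -5.42 ± 0.21 and Fh1, fumarate hydratase, at -3.99 ± 0.22. Chromatin regulators counted 21 lower, 1 higher and 3 not passed of 25 (21 and 1 when adjusted over the list alone, adjusted p = 2.18e-08, and 0.0397 with an estimated correlation). Hells, a helicase needed for DNA methylation, fell 55.4-fold, Uhrf1, which recruits the maintenance methyltransferase, 35.9-fold and Ezh2, the histone methyltransferase of Polycomb, had a difference of -4.44 ± 0.18. Of the 6 MLL leukaemia regulators, a list that is not independent evidence here, 5 fell (5 when adjusted over the list alone), among them the heterochromatin protein gene Cbx5, at -5.27 ± 0.29, Hmgb3, at -4.08 ± 0.25, and Myb, at -2.93 ± 0.24. That list fell at adjusted p = 0.0195, a call lost at adjusted p = 0.128 with an estimated correlation and at 0.137 without dim genes.

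Primary granule genes fell in 6 of 8 cases with 2 not passed (7 fell when adjusted over the list alone). The cystatin gene Cst7 fell by 6.77 ± 0.46, the serine protease genes Ctsg, cathepsin G, by 5.14 ± 0.58 and Elane, neutrophil elastase, by 4.71 ± 0.67. The differences of Cst7, Ctsg and Elane were -7.38, -5.92 and -5.64 without neutrophil array 1, and those of Ctsg and Elane -4.48 and -3.98 without neutrophil array 3. The list fell at adjusted p = 0.00548, a call lost at adjusted p = 0.37 with an estimated correlation and at 0.0808 without dim genes, and its median was 10.9 on neutrophil array 1 against 9.31 and 8.28 on the other two. Secondary granule genes were not called as a list, with 4 of 15 higher and 11 not passed (4 when adjusted over the list alone, adjusted p = 0.239), a median difference of -0.06, a mean of 0.72 and an upward test. Their median level on the Mac1+ arrays, 13.56 to 13.65, is near the top of the scale (maximum intensity 18326 to 22749), so a further rise may not show, though saturation was not tested. With quantile normalization they were called higher (adjusted p = 0.0339). The 4 included the collagenase gene Mmp8, which rose 88.5-fold, and Chil1, by 2.21 ± 0.26.

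Tertiary granule genes rose in 7 of 9 cases, with 1 lower and 1 not passed (7 and 1 when adjusted over the list alone, adjusted p = 0.000177, and adjusted p = 0.0619 with an estimated correlation). Next to Bst1, the metal transporter gene Slc11a1 rose 56.1-fold and Adam8, a membrane-bound metalloprotease, 49.0-fold. Chemotaxis and surface receptors counted 18 higher, 1 lower and 3 not passed of 22 (18 and 1 when adjusted over the list alone, adjusted p = 1.8e-09, and adjusted p = 0.0698 with an estimated correlation). Clec4d, a C-type lectin that binds fungal walls, rose by 5.64 ± 0.19, Tlr13, a sensor of bacterial ribosomal RNA, by 4.91 ± 0.16 and Cxcr2, the receptor that guides neutrophils out of the marrow, by 4.85 ± 0.15. Interferon response genes rose in 16 of 19 cases, with 2 lower and 1 not passed (16 and 2 when adjusted over the list alone, adjusted p = 1.73e-08, and 0.0397 with an estimated correlation), Ifi27l2a by 6.21 ± 0.31, the antiviral gene Rsad2 by 5.19 ± 0.26 and Usp18, which removes the ubiquitin-like modifier ISG15, by 5.13 ± 0.17.

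Inflammatory signal genes counted 15 higher, 1 lower and 4 not passed of 20 (15 and 1 when adjusted over the list alone, adjusted p = 5.18e-07, and adjusted p = 0.0698 with an estimated correlation), including the cytokine gene Il1b, 41.8-fold, the chemokine gene Ccl6, 40.7-fold, and Nlrp3, 28.2-fold. Stress and immediate early genes rose in 12 of 18 cases with 2 lower (12 and 2 when adjusted over the list alone, adjusted p = 0.000376, and adjusted p = 0.201 with an estimated correlation), among them Dusp1, a phosphatase of MAP kinases, by 4.17 ± 0.21 and Egr1 by 4.71 ± 0.64. Egr1 stood at 12.57, 10.36 and 9.60 on neutrophil arrays 1, 2 and 3, and its difference was 3.84 without array 1 and 5.33 without array 3 of these. Neutrophil array 1 lay above both others in 14 of the 18 genes of this list. Monocyte markers, which had fallen between the c-kit+ populations, rose in 10 of 20 cases with 2 lower and 8 not passed (10 and 2 when adjusted over the list alone, adjusted p = 0.00227, and adjusted p = 0.197 with an estimated correlation). Csf1r returned from 9.17 ± 0.30 to 13.14 ± 0.46, against 13.05 ± 0.05 in Mac1lo cells, and Ctss rose by 3.83 ± 0.17, whereas the adhesion molecule gene Vcam1 fell by 4.34 ± 0.21. Of 21 myeloid transcription factor genes, 11 rose and 4 fell (11 and 5 when adjusted over the list alone), among them Klf2, a factor of resting leukocytes, at 4.51 ± 0.21 and Gfi1, a repressor active in granulocyte precursors, at -3.35 ± 0.22. Their list rose at adjusted p = 0.0332, a call lost at adjusted p = 0.261 with an estimated correlation, at 0.0622 with arrays centred on their medians and at 0.0594 without neutrophil array 2. Stroma and endothelium markers were called higher at adjusted p = 0.0483 with 4 of 12 passing (2 when adjusted over the list alone), among them the collagen gene Col1a1 at 1.56 ± 0.23, and the call was lost at adjusted p = 0.567 with an estimated correlation. Its median was 6.93 on neutrophil array 1 against 5.69 and 5.58 on the other two, and the call was also lost without that array (adjusted p = 0.157), without Mac1+ array 2 (0.0673), without Mac1+ array 3 (0.0678) and under 7 of the other settings (0.0557 to 0.146). NADPH oxidase genes (1 of 7 lower, 1 when adjusted over the list alone) and stem and progenitor genes (4 higher and 6 lower of 25, the same numbers when adjusted over the list alone) were not called as lists (adjusted p = 0.932 and 0.518), although Myc, a driver of growth, fell by 4.64 ± 0.24.

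**Figure D2:**
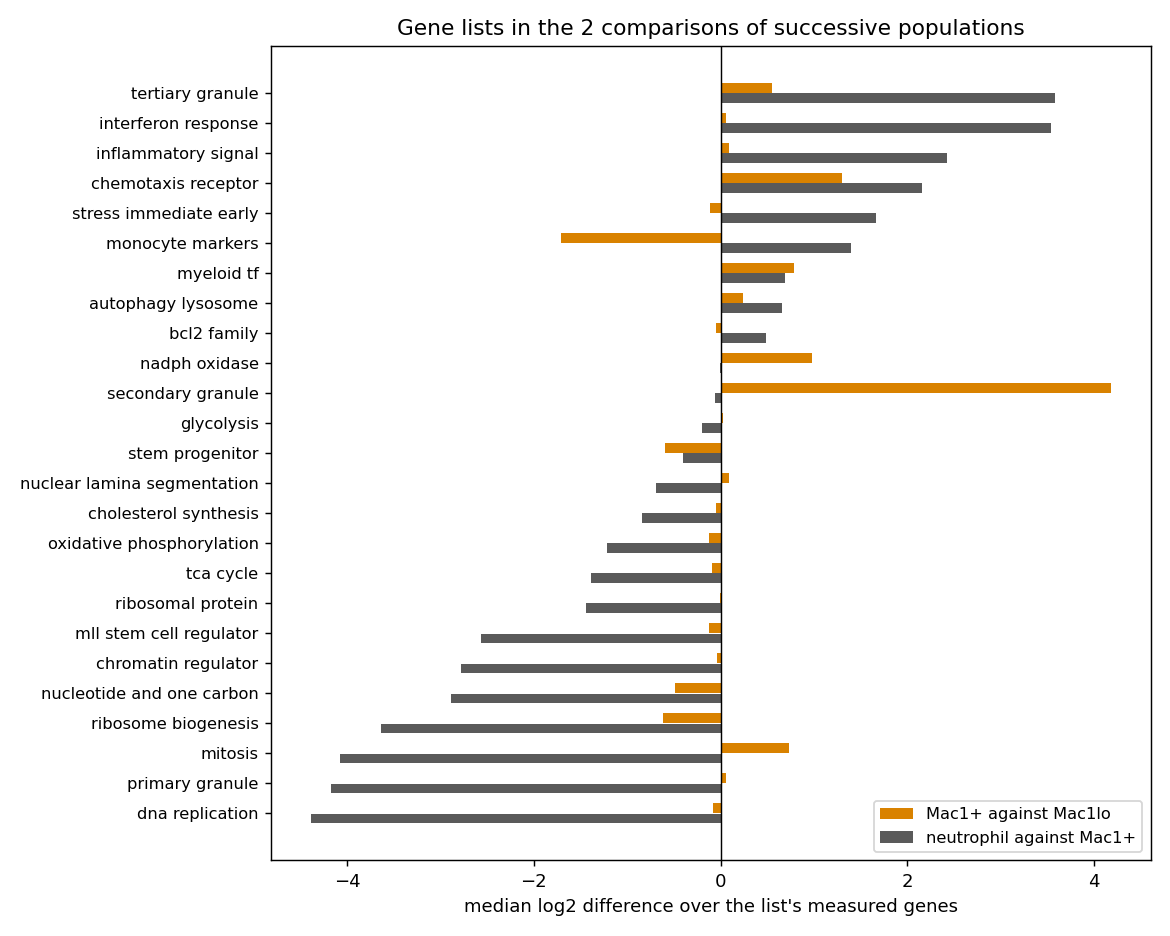
Median log2 difference over the measured genes of 25 lists, as bars from 0, for Mac1+ against Mac1lo cells (orange) and neutrophils against Mac1+ cells (grey), each from 3 arrays per population. Secondary granule genes had a median of 4.18 in the first and -0.06 in the other, while DNA replication genes had -0.08 and -4.38.

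Over all genes, limma called 3591 higher and 5163 lower in neutrophils than in Mac1+ cells, 48.1% of the 18194. Other genes among those with the largest differences were Slc15a3, a peptide transporter of lysosomes, 7.36 ± 0.21 higher, Arg2, mitochondrial arginase, 7.05 ± 0.14 higher, Uck2, a uridine-cytidine kinase, at -6.49 ± 0.17, and Hadh, an enzyme of fatty acid oxidation, at -6.21 ± 0.16. H2-Q10, Sirpb1a and Retnlb were more than 100-fold higher (203.3-fold, 187.5-fold and 153.2-fold), but each has close relatives that can share a probe set, so which member they report is uncertain. Of 33 lists 18 were called, 8 up and 10 down, and 4 of them (DNA replication, nucleotide and one-carbon, interferon response and chromatin) with an estimated correlation. The share of calls that were higher was 41.0%, 50.8% with quantile normalization and 58.9% with arrays centred on their medians, which moved the median of all genes from 0.05 to 0.33. Quantile normalization reversed 3 of the calls.

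Neutrophil arrays also differed from the others in their control probe sets and in their spread. Probe sets at the 3′ end of the added poly-A control transcripts stood at a log2 intensity, without the added 16, of 12.14 ± 0.66 on the 3 neutrophil arrays and 8.57 ± 0.49 on the 6 c-kit+ arrays (exact two-sided permutation p = 0.0119, the smallest this design allows). The SD of the deviations from the group mean was 0.617, 0.337 and 0.418 on neutrophil arrays 1, 2 and 3, against 0.177 to 0.251 on the c-kit+ arrays. In data simulated with this unequal spread, 15.6% of calls in the neutrophil against Mac1+ comparison and 11.4% in the neutrophil against Mac1lo comparison were false, above the intended 5%. These draws changed only 100 genes by each size and gave 24.3 and 16.5 false calls per draw. In the data 48.1% and 52.6% of genes were called, so the simulated shares are not those of the real calls.

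**Figure D3:**
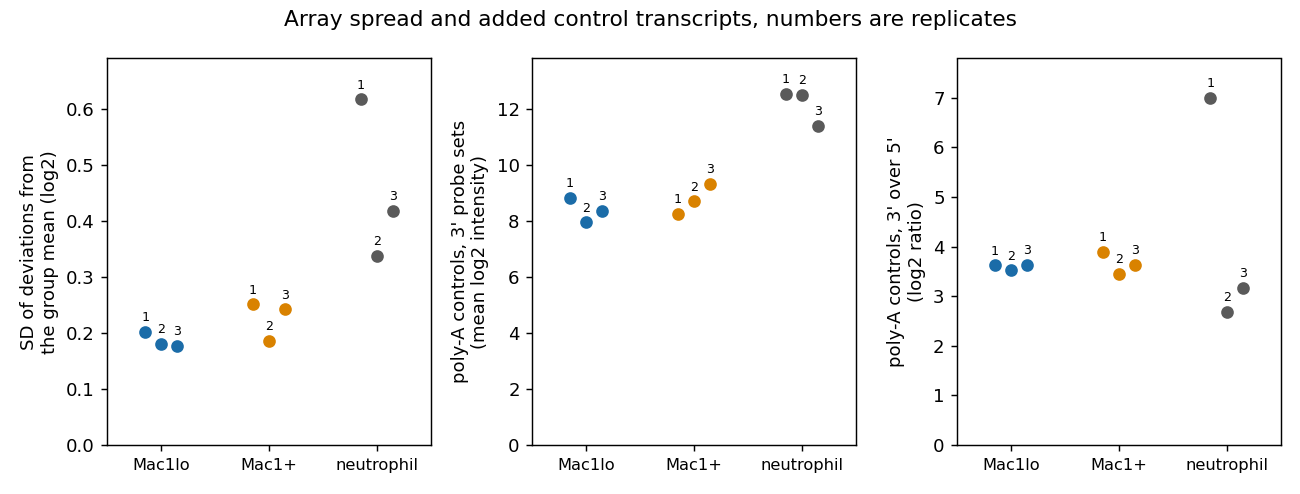
For each array, numbered by replicate within its population: the SD of its deviations from the group mean in log2 units, the mean log2 intensity (without the added 16) of the 3′ probe sets of the poly-A controls, and the log2 ratio of their 3′ over 5′ probe sets. Neutrophil array 1 has the largest SD (0.617) and the largest 3′ over 5′ ratio (7.0, against 2.68 and 3.16 on neutrophil arrays 2 and 3 and at most 3.90 elsewhere). All 3 neutrophil arrays have control signals of at least 11.38, above the highest c-kit+ array (9.33).

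The last comparison spanned the whole series, neutrophils against Mac1lo cells. Mmp9 was 361.6-fold higher in neutrophils (13.34 ± 0.14 against 4.84 ± 1.13, n = 3 each, difference 8.50 ± 0.49, adjusted p = 6.88e-07). Its levels on Mac1lo arrays 1, 2 and 3 were 6.14, 4.26 and 4.13, and without array 1 of these the difference was 9.15. Chil1 was 217.1-fold higher (difference 7.76 ± 0.26, adjusted p = 4.03e-08). Plbd1, a phospholipase B-like granule protein, was 268.4-fold higher and Cxcr2 145.2-fold higher. Cd34 fell by 6.69 ± 0.17, the nucleolar gene Tsr1 by 6.80 ± 0.21 and Cdk4, a kinase of the G1 phase, by 6.50 ± 0.43 (difference -7.11 without neutrophil array 1). Itgam rose by 5.10 ± 0.24 and Kit fell by 3.79 ± 0.38.

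Granule and receptor genes rose across this span in nearly every case: 14 of 15 secondary granule genes, 8 of 9 tertiary granule genes with 1 lower, and 21 of 22 chemotaxis and surface receptors, with the same numbers when each was adjusted over the list alone (adjusted p = 1.02e-09, 2.62e-05 and 1.05e-12). All 3 of these lists also passed with an estimated correlation (0.0397, 0.04998 and 0.04998). The tertiary granule and receptor lists share members, among them Itgam, whose antigen was used for the sort. Interferon response genes rose in 15 of 19 cases with 1 lower (15 and 1 when adjusted over the list alone, adjusted p = 9.01e-08, and 0.0397 with an estimated correlation), led by the oligoadenylate synthetase gene Oas3 at 5.10 ± 0.20. DNA replication genes (36 of 36), nucleotide and one-carbon genes (18 of 19) and chromatin regulators (21 of 25, 1 higher) fell, with the same numbers when adjusted over the list alone (adjusted p = 3.43e-17, 2.18e-08 and 1.62e-07), and these lists passed with an estimated correlation too (0.0397, 0.04998 and 0.0397). Primary granule genes fell in 7 of 8 cases (7 when adjusted over the list alone, adjusted p = 0.00413), a call lost at adjusted p = 0.364 with an estimated correlation and at 0.0564 without dim genes.

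Another 10 lists were likewise called only with the preset correlation. NADPH oxidase genes rose in 5 of 7 cases (6 when adjusted over the list alone, adjusted p = 0.00548, and adjusted p = 0.278 with an estimated correlation), Cybb by 2.08 ± 0.16. Myeloid transcription factors counted 15 higher and 4 lower of 21 (15 and 4 when adjusted over the list alone, adjusted p = 0.00121, and adjusted p = 0.138 with an estimated correlation), inflammatory signal genes 15 and 1 of 20 (15 and 1, adjusted p = 2.44e-06, and adjusted p = 0.0736 with an estimated correlation), and stress genes 12 and 4 of 18 (12 and 4, adjusted p = 0.00228, and adjusted p = 0.232 with an estimated correlation). Mitosis genes fell in 31 of 32 cases and ribosome biogenesis genes in 28 of 29 with 1 higher, as they did when adjusted over the list alone (adjusted p = 1.38e-11 and 4.02e-12, and adjusted p = 0.232 and 0.0698 with an estimated correlation). Ribosomal protein genes fell in 30 of 31 cases, oxidative phosphorylation genes in 33 of 34 and tricarboxylic acid cycle genes in 14 of 16, with the same numbers when adjusted over the list alone (adjusted p = 3.65e-08, 9.34e-09 and 1.37e-05, and adjusted p = 0.383, 0.197 and 0.232 with an estimated correlation). MLL leukaemia regulators, which are not independent evidence, fell in 5 of 6 cases (5 when adjusted over the list alone, adjusted p = 0.0109), a call lost at adjusted p = 0.105 with an estimated correlation and at 0.0917 without dim genes. Stem and progenitor genes counted 13 lower and 2 higher of 25 (13 and 2 when adjusted over the list alone), with Myc at -5.41 ± 0.24 and Sox4 at -4.22 ± 0.63 (-5.12 without neutrophil array 1). That list missed the threshold (adjusted p = 0.0505). It passed without Mac1lo array 1 (0.0473), Mac1lo array 3 (0.0439), Mac1+ array 1 (0.0456) or neutrophil array 2 (0.0467), and its lowest adjusted p was 0.0159, with arrays centred on their medians. Monocyte markers went both ways, with 8 higher, 7 lower and 5 not passed of 20 (10 and 7 when adjusted over the list alone, adjusted p = 0.879), a median of 0.33, a mean of -0.36 and an upward test.

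In total limma called 4109 genes higher and 5461 lower in neutrophils than in Mac1lo cells, 52.6% of the 18194. The share of calls that were higher was 42.9%, 50.6% with quantile normalization and 65.8% with arrays centred on their medians, where the median of all genes moved from 0.05 to 0.51. Quantile normalization reversed 13 of the calls.

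Read as successive steps, Mac1lo to Mac1+ cells and Mac1+ cells to neutrophils, the comparisons shared 1021 genes called in the same direction, 540 higher at both steps and 481 lower at both, and 538 called in opposite directions, 285 higher then lower and 253 lower then higher. Among mitosis genes 12 of 32 rose and then fell, and among monocyte markers 9 of 20 fell and then rose. Of 15 secondary granule genes 10 rose at the first step and did not pass at the other, and of 8 primary granule genes 6 did not pass at the first and fell at the other. Little room to rise may have been left for secondary granule genes at the latter step, which was not tested. Independent lists of the same lengths would share 511.2 genes in the same and 523.7 in opposite directions. In 20 simulations without any effect the mean was 0 of either kind. No gene differs in such data and hardly any can be called, so that 0 is no reference for the overlap of real calls. The reference of independent lists counts all 18194 genes as equally callable. Yet 1986 of the 2151 genes called at the first step were among the 10916 not dim, so it is no firm chance level. With dim genes left out, 1328 were shared in the same and 686 in opposite directions. The lists then had other lengths, 1452 higher and 1104 lower at the first step and 2723 and 5062 at the other. What independent lists of those lengths would share was not computed, so 511.2 and 523.7 are no reference for these counts. Across genes, which are not independent replicates, the log2 differences of the steps had a Pearson r of 0.0946 against -0.499 without effects, and a covariance of 0.0942 against -0.0426. Both steps use the same 3 Mac1+ arrays, too few to split, on opposite sides of the difference. Their chance values pull the steps apart, which alone makes r and covariance negative without effects. Part of the 538 may therefore come from the shared arrays. The number in the same direction was 623, 632 and 662 without Mac1lo array 2, Mac1lo array 3 and Mac1+ array 2, and 2053 without neutrophil array 1. In opposite directions it was 353, 325 and 313 without Mac1lo arrays 1, 2 and 3, 350, 326 and 332 without Mac1+ arrays 1, 2 and 3, and 1178 without neutrophil array 1.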

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

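All tests of explanations in this part were chosen only after the result was seen. Control transcripts, which the comparisons do not use, were brighter on the neutrophil arrays. Probe sets at the 3′ end of the poly-A controls, transcripts added to the RNA before amplification, stood at 12.14 ± 0.66 (n = 3) against 8.57 ± 0.49 on the c-kit+ arrays (n = 6), a difference of 3.58. Those of bioB, a control added at hybridisation, stood at 10.57 ± 1.21 against 8.41 ± 0.22, a difference of 2.16. Each had an exact two-sided permutation p of 0.0119, the smallest this design allows.

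One candidate explanation of the brighter controls is less RNA of the cells per added control transcript in the neutrophil samples. No value here tests it, since the poly-A difference of 3.58 is the observation that raised it. It stays open, because other amounts of control could have been added and bioB, which enters after amplification, was brighter too. All of the brighter arrays hold neutrophils, so the handling of the samples and the population cannot be told apart. A biological difference in RNA content between the populations was not tested. For scale, 239 genes were called higher in neutrophils than in Mac1+ cells by more than 3.58, and 336 than in Mac1lo cells, while 710 and 946 were called higher by more than 2.16.

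Neutrophil array 1 departed from the other 2 neutrophil arrays, with an SD of deviations of 0.617 against 0.337 and 0.418 and a mean correlation with its group of 0.933. Its signal distribution alone is argued against, since quantile normalization left an SD of 0.683 against 0.371 and 0.471. Mitosis genes, abundant in both c-kit+ populations, argue against c-kit+ cells as the source of the whole departure. Their median was -0.482 from the other 2 (27 of 32 below both), and Kit stood at 6.79 against 8.28 and 8.44. That list was chosen after the values were seen, and other lists lay higher on this array. Medians were 2.13 for primary granule genes (7 of 8 above both), 0.62 for ribosomal protein genes (28 of 31), 0.88 for MLL leukaemia regulators and 0.36 for ribosome biogenesis genes. Stem and progenitor genes had 0.40 and DNA replication genes 0.13 (17 of 36 above both and 11 below). Such cells as the source of a part of the departure are not excluded. A stronger loss of 5′ sequence stays open, because the poly-A 3′ over 5′ log2 ratio exceeded the highest of the other 8 arrays by 3.1, whereas that of actin, 0.63, lay within the range of the others (0.61 to 1.32) and that of Gapdh, 1.43, above theirs (0.94 to 1.30). The poly-A controls were dimmer on the c-kit+ arrays. The closest comparison of the poly-A ratio is therefore with neutrophil arrays 2 and 3 (2.68 and 3.16). No biological explanation was tested.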

How the results depend on the processing

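No setting was added later. Named genes kept direction and side of the threshold in 7419 cases over all settings, lost their call in 270, gained one in 16 and reversed in 6. Lists did so in 1996, lost it in 54 and gained it in 26, and 0 reversed. When arrays were left out in turn, 175 gene calls and 4 list calls were lost. Centred arrays gave 6126 and 8142 genes higher in neutrophils against Mac1+ and against Mac1lo cells. Every probe set gave 8916 higher and 9469 lower against Mac1+ cells and 10113 and 10187 against Mac1lo cells, with more features tested, and no list test. A fit of only the 2 groups, without the neutrophil spread, gave 2274 higher and 2235 lower in Mac1+ against Mac1lo cells. Array weights gave 2904 and 2856 there, 5829 and 6202 higher in neutrophils against Mac1+ and Mac1lo cells, and 2846 genes in the same and 1800 in opposite directions at both steps. With an estimated correlation 2, 4 and 7 lists were called. A change of at least 2-fold, which only removes calls, left 583 higher and 623 lower in Mac1+ against Mac1lo cells, 2220 and 2682 higher in neutrophils, and 459 and 256 at both steps. Without 1 array, Mac1+ against Mac1lo cells had 710 (without Mac1lo array 3) to 2190 (without neutrophil array 1) genes higher and 599 (Mac1lo array 2) to 1986 (neutrophil array 1) lower, and both steps shared 623 to 2053 in the same and 313 to 1178 in opposite directions.

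The cause of the 6 reversals was not tested, nor that of the counts with centred arrays and array weights. Col1a2, neutrophil against Mac1+ became -0.142 with an offset of 1, and Ebf1, neutrophil against Mac1+ 0.003 with the mean of a gene's probe sets. Without x and s probe sets H2-Ab1, neutrophil against Mac1+ became 0.079, Igll1, neutrophil against Mac1+ 0.286, Igll1, neutrophil against Mac1lo 0.194 and Xist, neutrophil against Mac1lo -0.029. Signal over background limits dim genes, and leaving them out kept 10916 genes. The replicate block gave 868 higher and 795 lower in Mac1+ against Mac1lo cells, ended 10 named calls and changed 0 lists. Deviations of arrays with the same number had correlations of -0.307 to 0.132, over 0.1 in 1 of 9 pairs, and 3 of 9 arrays correlated best with their own number, so the numbers were not taken to pair the samples.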

Other observations

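Tests of explanations for the monocyte genes were chosen only after the result was seen, as were the genes of the Schlafen, CD300, MS4A, S100 and interleukin-18 groups, while the regroupings of arrays were planned. Several lists outside the called ones held large changes of single genes. In the Bcl2 family, which controls cell death, neutrophils had 7 of 13 genes higher and 2 lower than Mac1+ cells (7 and 2 when adjusted over the list alone). The pro-apoptotic genes Bmf, Pmaip1 and Bbc3 were 3.34 ± 0.50, 2.75 ± 0.26 and 2.45 ± 0.22 higher (Bmf by 2.68 without neutrophil array 1). As a list they were not called (adjusted p = 0.11), but passed with quantile normalization (0.038) and with the mean of a gene's probe sets (0.0201). Between the c-kit+ populations 1 rose, Bcl2l1, but not with the mean of its probe sets (adjusted p = 0.539), and 1 fell, Bcl2, with a difference of -2.72 ± 0.47 (1 and 2 when adjusted over the list alone, adjusted p = 0.786). Against Mac1lo cells neutrophils had 6 higher and 2 lower (6 and 2, adjusted p = 0.223). Autophagy and lysosome genes counted 12 higher and 5 lower of 22 in neutrophils against Mac1+ cells (13 and 5 when adjusted over the list alone, adjusted p = 0.0638), with the kinase gene Ulk1 at 2.33 ± 0.18 and Atg7 at 2.04 ± 0.12. That list passed with quantile normalization (adjusted p = 0.02), an offset of 64 (0.0488), without dim genes (0.0179) and without Mac1+ array 3 (0.0439). It had 1 higher and 4 lower in Mac1+ against Mac1lo cells (2 and 4, adjusted p = 0.936), with a median of 0.24, a mean of -0.20 and an upward test, and 10 and 6 in neutrophils against Mac1lo cells (10 and 6, adjusted p = 0.278).

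Cholesterol synthesis genes were lower in neutrophils than in Mac1+ cells in 8 of 17 cases and higher in 2 (8 and 2 when adjusted over the list alone, adjusted p = 0.0861), led by Fdps at -3.39 ± 0.22 and Dhcr7 at -3.36 ± 0.19. Against Mac1lo cells 10 were lower and 4 higher (10 and 4, adjusted p = 0.194). Between the c-kit+ populations only Fdft1 passed, higher by 0.97 ± 0.19 (1 gene also when adjusted over the list alone, adjusted p = 0.743), but not without Mac1lo array 2, Mac1lo array 3 or Mac1+ array 2 (adjusted p = 0.0501 to 0.0535) or with the mean of its probe sets (0.135). The median of this list was -0.05 (mean 0.001) and its test upward. Of 9 genes of the nuclear lamina, 5 were lower and 1 higher in neutrophils against Mac1+ cells (5 and 1 when adjusted over the list alone, adjusted p = 0.0861). Banf1, a chromatin-binding partner of the lamina, had a difference of -4.38 ± 0.14 and Lmnb2, lamin B2, one of -3.71 ± 0.14. Against Mac1lo cells 5 were lower and 1 higher too (5 and 1, adjusted p = 0.26), and between the c-kit+ populations 0 passed in limma (0 when adjusted over the list alone, adjusted p = 0.25), with 3 at an unadjusted p under 0.05. Glycolysis genes went both ways. Mac1+ cells had 3 of 17 higher and 2 lower (4 and 2 when adjusted over the list alone, adjusted p = 0.297), among them Pfkfb4 at 2.28 ± 0.17 and Pfkl at -1.05 ± 0.17, and the glucose transporter gene Slc2a3, at 2.29 ± 0.16, lost its call without probe sets able to bind several transcripts (adjusted p = 0.971). Neutrophils had 3 higher and 5 lower than Mac1+ cells (3 and 5, adjusted p = 0.794), with Slc2a1 at 2.63 ± 0.27 and Tpi1 at -1.39 ± 0.15, a median of -0.20, a mean of 0.04 and a downward test. Against Mac1lo cells these were 4 and 7 (4 and 7, adjusted p = 0.984), with a median of -0.06, a mean of 0.28 and an upward test.

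Markers of other marrow cells, apart from those of monocytes, dendritic cells and stroma, were called in none of the comparisons. Counts are given as higher and lower, first over all genes and then adjusted over the list alone, for Mac1+ against Mac1lo, neutrophil against Mac1+ and neutrophil against Mac1lo in turn. Eosinophil markers, 7 in number, had 1 and 0 (1 and 0), 1 and 3 (2 and 3), and 2 and 1 (2 and 1), at adjusted p = 0.594, 0.997 and 0.769, and Siglecf was 1.55 ± 0.16 higher in Mac1+ than in Mac1lo cells. Of 11 basophil and mast cell markers 1 and 1 (1 and 1), 3 and 3 (3 and 3), and 4 and 3 (4 and 3) passed, at adjusted p = 0.794, 0.889 and 0.981, with Mcpt8 at -3.79 ± 0.29 in neutrophils against Mac1+ cells. The 15 erythroid markers had 2 and 0 (2 and 0), 2 and 3 (2 and 3), and 3 and 5 (3 and 5), at adjusted p = 0.578, 0.879 and 0.971. Hemgn was 2.04 ± 0.19 higher in Mac1+ cells, and Tfrc, the transferrin receptor of dividing cells, had -4.40 ± 0.38 in neutrophils against them. Megakaryocyte markers, 11 in all, had 2 and 0 (2 and 0), 3 and 0 (3 and 0), and 3 and 0 (3 and 0), at adjusted p = 0.513, 0.0858 and 0.0858, and in the last passed without dim genes (0.0374). B cell markers, 16 in all, had 0 and 1 (0 and 1), 0 and 3 (0 and 3), and 0 and 4 (0 and 4), at adjusted p = 0.345, 0.786 and 0.547, with Jchain at -4.03 ± 0.60 in Mac1+ against Mac1lo cells (-3.19 without Mac1lo array 1). The 16 T and NK cell markers had 0 and 1 (0 and 1), 5 and 1 (5 and 1), and 6 and 1 (4 and 1), at adjusted p = 0.73, 0.118 and 0.278, with Cd3d 2.78 ± 0.17 higher in neutrophils than in Mac1+ cells. Dendritic markers were not called in neutrophils against Mac1+ cells (2 and 2 of 14, 2 and 2, adjusted p = 0.451), where Cd74 rose by 3.70 ± 0.21, nor against Mac1lo cells (2 and 5, 2 and 5, adjusted p = 0.997). Stroma markers had 0 and 1 of 12 (0 and 1, adjusted p = 0.594) in the first comparison and 3 and 1 (3 and 1, adjusted p = 0.186) in the last. Median and mean differed in sign, with upward tests, for eosinophil markers (0.25 and -0.27, then 0.10 and -0.02), erythroid markers (0.31 and -0.35, then 0.21 and -0.22), basophil markers against Mac1+ cells (0.08 and -0.43) and dendritic markers against Mac1lo cells (0.09 and -0.05). With downward tests they did so for B cell markers against Mac1+ cells (0.07 and -0.45) and basophil markers against Mac1lo cells (0.03 and -0.50). Of 4 sex genes, 0, 2 and 3 passed in the comparisons in turn (0, 3 and 4 when adjusted over the list alone), and in neutrophils against Mac1+ cells Uty, at -1.68 ± 0.37, and Eif2s3y, at 0.78 ± 0.14, passed in opposite directions. The call of Uty was lost with quantile normalization and with the mean of its probe sets (adjusted p = 0.0928 to 0.358), and that of Eif2s3y with the mean of its probe sets (0.0693).

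Some gene families, of which single members are in the lists, moved apart within the family or between the steps. Probe sets of such relatives can bind each other's transcripts, so which member is reported is uncertain. Schlafen genes, regulators of lymphoid and myeloid growth, had Slfn1 higher by 1.35 and then by 6.79 and Slfn4 by 3.48 and 2.82, while Slfn9 had -5.18 in neutrophils against Mac1+ cells. Slfn8 had -0.67 at the first step, a call lost with quantile normalization (adjusted p = 0.116), and Slfn5 rose by 3.90 at the other. Of the CD300 receptors, Cd300lf rose by 4.52 and 2.39 and Cd300lb had -1.60 and then 4.51. Ms4a6c, of the MS4A family, had -4.02 at the first step, and Ms4a4b -4.41 and then 2.03. S100a9, a subunit of calprotectin, rose by 2.84 at the first step, and S100a6 had -1.05 and then 6.62. Both chains of the interleukin-18 receptor and its decoy rose at both steps, with Il18r1 at 2.28 and 3.34 and Il18bp at 1.19 and 3.16.

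Monocyte genes were higher in Mac1lo than in Mac1+ cells. Both had been sorted with c-kit and without a set of antigens of the lymphoid and erythroid lineages. That set was not one of the monocyte lineage, so it was no guard against cells of that lineage. Over the 16 of 20 measured members above the median gene (in Mac1lo cells F13a1 stood at 13.58, Csf1r at 13.05 and Ctss at 12.83) the median was -2.12 ± 0.56, and 3 of the 21 genes written for the list are also in other lists. For medians of gene sets in this paragraph, ± is a standard error over genes, which are not replicates. Macrophages stay open, because 4 of 6 of their genes lay below the median gene, although their median difference was 0.66 ± 0.49 (C1qa 0.71, C1qb 0.13, C1qc 0.84, Spic 0.60, Vcam1 2.39, Apoe -0.44). Kit differed by 0.079 ± 0.375, an error over arrays from the fit shared with the more variable neutrophil arrays. On single arrays Kit lay at 11.56 to 11.66 in Mac1lo and 11.64 to 11.77 in Mac1+ cells. These overlapping ranges show no clear drop of Kit in Mac1lo cells. A small share of mature monocytes without c-kit stays open, since it could not be told from them. A general admixture of other marrow cells stays open too, because few markers lay above the median gene: 5 B cell markers had -0.631 ± 0.908 (-0.11 over all 16), 2 dendritic markers -1.36 (-0.22 over all 14), 2 stroma markers -0.87, 2 T and NK cell markers -0.30, 1 eosinophil marker 1.55, and basophil, megakaryocyte and erythroid markers -0.29 ± 0.43, 0.42 ± 0.75 and 0.62 ± 0.68. A biological candidate, that cells able to form monocytes are more frequent among c-kit+ Gr1+ cells with little Mac1, may account for it and cannot be told apart from these open ones.

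Regroupings of the arrays were counted for each result. Of the 10 splits of 6 arrays, too few for a share under 0.05, only the real one (1 of 10) gave as many genes for each of the counts 1148, 1003, 3591, 5163, 4109 and 5461, and the highest of the other splits was 0. For lists, 4 of 10 splits, with the real one counted, gave as many as the real 11 in Mac1+ against Mac1lo cells, with 12 in the highest other, and 1 of 10 as many as the real 18 in each of the others, with 15 and 17. Camera with the preset correlation thus called up to 17 lists in splits where 0 genes passed. Every such split mixes the populations unequally and keeps part of their difference. These list calls are therefore no measure of false calls. For the genes called at both steps, only the real one (1 of 100 regroupings of the 9 arrays) gave as many in the same direction (1021, highest other 0) and 1 of 100 in opposite directions (538, highest other 27). Chance is not excluded by this, because groups that mix such different populations have a wide spread and few calls. These regroupings mix the populations and do not test the overlap itself. Nor do the 523.7 genes that independent lists would share set a firm chance level for the 538, since dim genes were called less often.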
